A study of Homo sapiens with 6 samples.

How the data were processed

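RNA-seq was analysed for 6 libraries of 786-O cells, a line derived from a clear cell renal cell carcinoma, in 2 groups of 3 that carried a scrambled control shRNA or an shRNA against IMPDH1. Groups and replicate numbers were taken from the labels. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The series description speaks of 3 separate shRNAs that target IMPDH1, and which hairpin each IMPDH1 library carried is not given in the sources used here. The spread between these 3 libraries, and the p-values that rest on it, may therefore be that of replicates of 1 hairpin or of different hairpins.

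The authors deposited 1 table of FPKM values (fragments per kilobase of transcript scaled to the mapped fragments of the library) with 1 row per gene and 1 column per library. Trimmomatic, HISAT2, Cufflinks, HTSeq, DESeq and the genome build GRCh38 are named, without versions, in the submitters' processing notes, and which of them produced the FPKM values is not given in the sources used here. The table had 19974 rows, of which 19973 were marked protein-coding. Gene names in 28 rows had been turned into dates and were replaced through their GeneID. GeneIDs of 19566 rows matched the RefSeq gene table of GRCh38, which gave positions. The 47 rows of Y-linked genes were left out of every step, which is an exception to the rule for named genes. This left 19927 genes.

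The deposited FPKM of the analysed genes summed to between 365336 and 376501 in the control libraries. In the IMPDH1 shRNA libraries the sums were lower, between 343571 and 346138. Between 14261 and 14447 genes lay above 0 in a control library, against 13745 to 13813 in an IMPDH1 shRNA library. FPKM values carry no counts, so the absolute depth is unknown and no counting interval is given. Low values were searched for the step that 1 read is worth, among genes under 0.5 FPKM in both libraries of a pair and listed at 0 in at least 2 of the 6. Ratios of low values within a group had a sharp most common value, which put the depth of control replicate 1 at 1.22 times that of control replicate 2 and 1.27 times that of control replicate 3. The depths of the IMPDH1 shRNA libraries were within 1.04 times of each other by the same measure. No relative depth could be read between the groups. An exact 0 can be a failed estimate in this table. In 9 tested genes a library was listed at 0 beside at least 5 FPKM in another library of its group, and these genes are given as values per library.

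Values were transformed as log2(FPKM + 0.5), and 10797 genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance and Benjamini-Hochberg adjustment at 0.05. Fold changes are on that scale, which understates the change of low genes. Results are given as IMPDH1 shRNA over control shRNA, with standard errors from limma. An exact two-sided permutation test of 3 against 3 libraries cannot give a p under 0.1. The limma step was tested on simulated data for this comparison, with 200 of the 10797 genes changed in each of 5 rounds. It recovered 84.8% of genes changed 1.5-fold, 94.9% of those changed 2-fold and 99.7% of those changed 4-fold, and 5.58% of its calls were false. Unchanged genes were drawn as independent noise around the same mean in both groups. These shares therefore need not hold for the real data, in which 74.2% of genes were called.

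Gene lists were fixed before the data were examined. Of their 944 genes, 931 matched a row, and the other 13, the mitochondrial mRNAs, were not analysed here. Lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with the other genes, and adjusted over 35 lists. Camera with an estimated correlation and fry, which tests a list by itself, were run beside it. Counts of members past the threshold are over all genes tested unless given as adjusted over the list alone.

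Genes were named by a rule fixed before the data were examined. It takes IMPDH1, IMPDH2, YBX1, YBX3, CTPS1 and GMPS; the 10 largest rises and 10 largest falls among genes with a mean of at least 5 FPKM, an adjusted p under 0.05 and no overlap between the groups; up to 4 members of each list with the largest change; and the 3 smallest p-values in each direction. Genes named outside it are said to be so, and some genes that the rule takes are not reported here.

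Alternatives fixed before the data were examined were pseudocounts of 0.1 and 1, no filter, a filter at a mean of 5 FPKM, 3 other scalings, limma without the trend or with a robust prior, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were setting the suspect zeros to missing, removing a loess trend on transcript length, GC content and expression, and subtracting the median of each 20 Mb window. Transcript length and GC content came from the longest protein-coding GENCODE 29 transcript of each GeneID and were found for 99.6% of tested genes. Figures and position tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The comparison of exact zeros with values near 0 took the place of a simulation that could not have produced a 0, and its allowance for counting error was added after the counts were seen.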

Results

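Transcript levels were measured by RNA-seq of total RNA in 786-O clear cell renal carcinoma cells carrying a scrambled control shRNA (3 libraries) or an shRNA against IMPDH1 (3 libraries). The design implies 1 comparison, which asks how lowering IMPDH1, an enzyme of guanine nucleotide synthesis, changes the transcriptome of these cells. Between 10646 and 10718 genes reached 1 FPKM in a library. Pearson correlations of log2 values across genes were 0.987 to 0.992 within a group and 0.904 to 0.916 between groups. The median SD between replicates was 0.061 (log2) in the control group and 0.078 in the IMPDH1 shRNA group.

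IMPDH1 (GeneID 3614; GRCh38 chromosome 7, 128392277 to 128409982) stood at 48.9, 47.4 and 45.0 FPKM in the control libraries and at 12.2, 13.2 and 12.7 FPKM in the IMPDH1 shRNA libraries. The IMPDH1 shRNA group kept 26.9% of the control level, and the log2 fold change was -1.85 ± 0.05 (SE; limma, adjusted p = 2.91e-08; n = 3 per group). The exact permutation test gave p = 0.1, the smallest it can give. IMPDH2, the second IMP dehydrogenase, fell from 121 ± 1.71 to 92.3 ± 1.85 FPKM (SD, n = 3; limma, adjusted p = 1.05e-05). Its log2 fold change of -0.39 became -0.24 with quantile normalization, -0.16 after removal of a trend on length, GC and expression and -0.12 with the medians of 20 Mb windows subtracted (limma, adjusted p = 0.0116). GMPS, which makes GMP in the next step, fell from 39.4 ± 0.22 to 29.7 ± 0.92 FPKM (limma, adjusted p = 2.51e-05). YBX1, which encodes YB-1, rose from 433 ± 15.3 to 561 ± 37.1 FPKM (limma, adjusted p = 2.01e-04), and its relative YBX3 rose to 123% of the control level. After removal of the trend the log2 fold changes of 0.37 for YBX1 and 0.30 for YBX3 became 0.62 and 0.53; quantile normalization gave 0.65 for YBX1, and subtracting window medians gave 0.16 for YBX3. CTPS1, the CTP synthase whose filaments form cytoophidia, stood at 23.9 ± 0.47 and 21.6 ± 2.79 FPKM and did not pass the test (limma, adjusted p = 0.152). Its log2 fold change of -0.15 became -0.22 without IMPDH1 shRNA replicate 2 (limma, adjusted p = 0.036) and -0.26 with window medians subtracted (limma, adjusted p = 0.0223), which passed, and -0.04 without replicate 3 or with values rescaled to 1 common sum and -0.08 with quantile normalization, which did not.

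**Figure D1:**
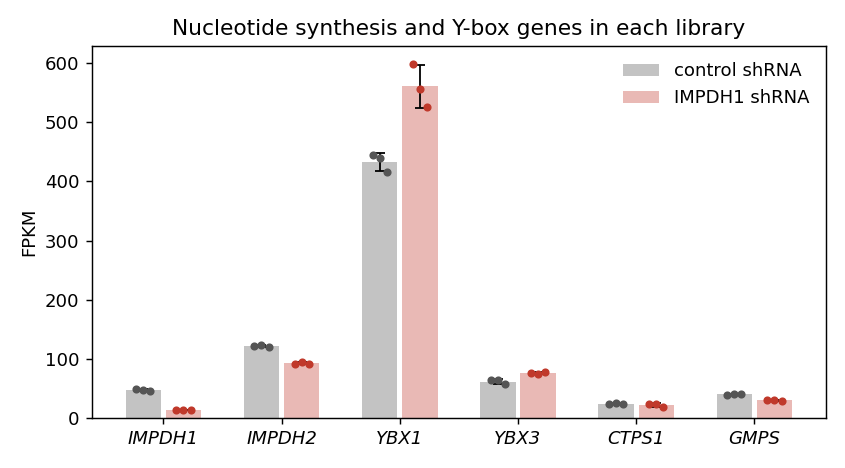
FPKM of IMPDH1, IMPDH2, YBX1, YBX3, CTPS1 and GMPS in the control shRNA (grey) and IMPDH1 shRNA (red) libraries. Bars are means of 3 libraries, error bars are SD and points are libraries; IMPDH1 fell to 26.9% of the control level, while CTPS1 overlapped between the groups.

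Of 10797 genes tested, 3874 rose and 4134 fell in the IMPDH1 shRNA group (limma, adjusted p under 0.05), together 74.2% of genes, and 592 rose and 622 fell at least 2-fold. With each library rescaled to 1 common sum, 839 rose and 553 fell at least 2-fold. The median absolute log2 fold change was 0.37. A difference between the groups in how values were scaled per gene would also count as a change here, and its share was not measured. The 3 values of one group did not overlap the 3 of the other in 77.4% of genes, against 10% by chance. Genes in the same 20 Mb window of an autosome moved together, with window medians from -0.69 to 0.56 (log2), and genes with shorter transcripts had lower fold changes, with medians of -0.26 among the shortest of 5 equal classes and 0.16 among the longest. Genes with higher GC content also had lower fold changes, with medians of 0.20 in the lowest of 5 equal GC classes and -0.19 in the highest.

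The 10 largest rises included genes of secreted and acute phase proteins. CXCL1, a neutrophil chemokine, rose from 3.51 ± 0.40 to 332 ± 55.2 FPKM (log2 fold change 6.37 ± 0.12; limma, adjusted p = 5.32e-09), and CXCL8, another one, from 2.98 ± 0.13 to 219 ± 42.8 FPKM. LCN2, an iron-siderophore binding protein, rose from 0.13 ± 0.02 to 45.0 ± 3.77 FPKM, and complement C3 from 3.40 ± 0.27 to 131 ± 5.41 FPKM. The serum amyloid genes SAA1 (9.43 ± 0.60 to 338 ± 15.1 FPKM) and SAA2 (0.71 ± 0.15 to 50.6 ± 1.54 FPKM) rose, and their near-identical sequences make the split between them uncertain. GDF15, a stress-induced cytokine, rose from 1.08 ± 0.12 to 55.7 ± 10.9 FPKM, with LCP1, FCAMR and ALDH2 also among the 10 largest. The largest fall was in the sulfotransferase CHST1, from 17.5 ± 2.47 to 0.20 ± 0.08 FPKM. NTRK3, a neurotrophin receptor, fell from 22.6 ± 1.18 to 0.85 ± 0.05 FPKM, PGF, a growth factor of the VEGF family, from 16.6 ± 2.40 to 0.62 ± 0.22 FPKM, and SCARA3 from 9.84 ± 0.35 to 0.25 ± 0.03 FPKM. LYPD1 and SIGLEC15 also fell, with log2 fold changes of -3.60 and -3.21, as did IFITM2, with -4.36, whose reads can be shared with IFITM3. RNH1 and TRAPPC4 are among the 10 largest falls but were unstable within the control group. The log2 fold change of RNH1 went from -3.45 to -4.23 without control replicate 3, and TRAPPC4 from -3.18 to -2.48 without control replicate 1 and to -4.27 without control replicate 2. TRAPPC4 lost its call with a robust prior (limma, adjusted p = 0.0541; 0.00546 in the main test).

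**Figure D2:**
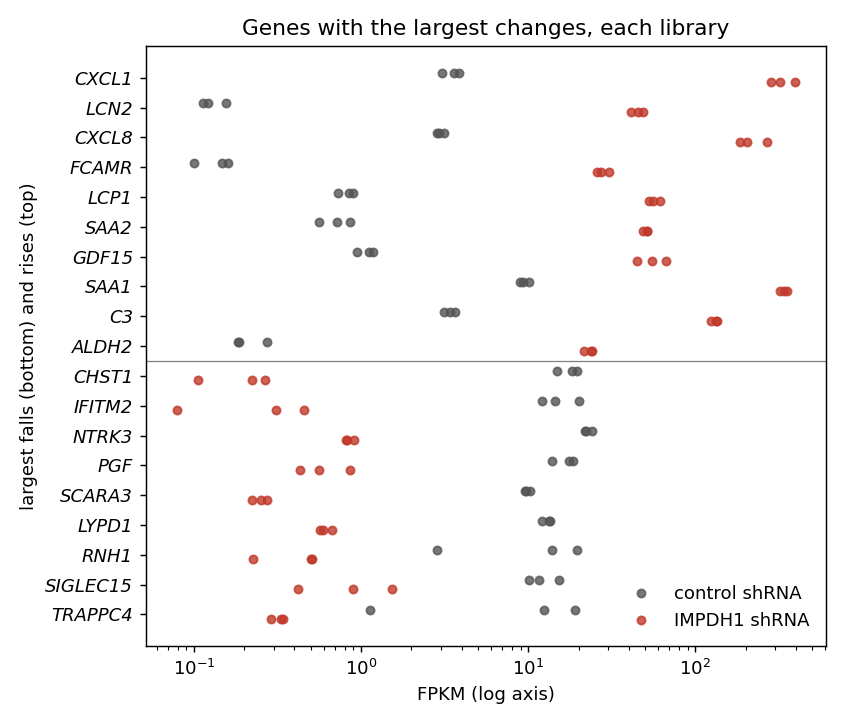
FPKM (log axis) of genes with the largest rises (top) and the largest falls (bottom), 1 point per library, control shRNA in grey and IMPDH1 shRNA in red. The groups are apart in each gene by the rule that chose them, while RNH1 and TRAPPC4 spread widely among the control libraries.

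In the lists that follow, counts adjusted over the list alone were the same as those over all genes, except where both are given. Target genes of ATF4, the transcription factor of the integrated stress response, rose. All 28 tested members rose, with a median log2 fold change of 1.32 (camera, adjusted p = 1.51e-09; adjusted p = 0.458 with an estimated correlation). CTH, an enzyme of cysteine synthesis, rose from 2.04 ± 0.24 to 15.7 ± 3.502 FPKM, NUPR1 from 5.45 ± 0.32 to 35.6 ± 4.67 FPKM and CEBPB from 22.03 ± 1.97 to 111 ± 14.96 FPKM. Of 12 genes of one-carbon and serine metabolism, 10 rose and 2 fell. The list's median was 0.61 (camera, adjusted p = 0.00837; adjusted p = 0.31 with an estimated correlation). They include PSPH (log2 fold change 1.59) and PSAT1 (1.47), which make serine, and mitochondrial MTHFD2 (1.33).

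Genes of cholesterol synthesis rose in 23 of 24 cases and fell in 1. Members had a median of 1.24 (camera, adjusted p = 2.04e-09; adjusted p = 0.0708 with an estimated correlation). MSMO1 rose from 12.9 ± 0.39 to 96.3 ± 1.83 FPKM and HMGCS1, the HMG-CoA synthase, from 24.8 ± 0.29 to 135 ± 2.74 FPKM. Of 18 genes of fatty acid synthesis and lipid storage, 11 rose and 3 fell. The median over members was 0.63 (camera, adjusted p = 0.00769; adjusted p = 0.31 with an estimated correlation). The desaturase SCD rose from 136 ± 1.42 to 604 ± 37.7 FPKM, and the lipid droplet genes HILPDA and PLIN2 had log2 fold changes of 2.37 and 1.87.

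Of 27 NF-kB target and cytokine genes, 20 rose and 4 fell, or 21 and 4 adjusted over the list alone, with a median of 1.92 (camera, adjusted p = 4.95e-06; adjusted p = 0.399 with an estimated correlation). Beside CXCL1 and CXCL8, the chemokine CCL20 rose from 0.07 ± 0.08 to 7.74 ± 1.63 FPKM and CSF2 from 0.51 ± 0.14 to 10.6 ± 3.59 FPKM. Interferon response genes moved the other way, with 19 of 30 lower and 6 higher. The list median was -0.40 (camera, adjusted p = 0.0265; adjusted p = 0.458 with an estimated correlation). The call was lost with a filter at a mean of 5 FPKM (median -0.41; camera, adjusted p = 0.107; range over 19 alternatives 0.00622 to 0.107). IFITM3 fell from 196 ± 15.8 to 53.1 ± 5.42 FPKM and BST2, which tethers virions, from 112 ± 8.15 to 38.7 ± 1.14 FPKM. Of 12 antigen presentation genes, 9 fell and none rose. The list's median was -0.60 (camera, adjusted p = 0.00837; adjusted p = 0.458 with an estimated correlation). Among them were CD74 (18.5 ± 0.19 to 3.12 ± 0.16 FPKM) and HLA-B (323 ± 17.4 to 157 ± 7.53 FPKM), whose reads can be shared with other HLA genes. The median became -0.29 without a filter and -0.40 after removal of the trend, and the call held.

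Genes of G2 phase and mitosis fell in 27 of 32 cases and rose in 1, or 28 and 1 adjusted over the list alone. Members had a median of -0.77 (camera, adjusted p = 1.73e-08; adjusted p = 0.31 with an estimated correlation). The mitotic kinesin KIF20A fell from 71.4 ± 0.33 to 23.8 ± 0.90 FPKM, UBE2C from 249 ± 6.89 to 103 ± 5.64 FPKM and cyclin B1 (CCNB1) from 105 ± 2.06 to 46.5 ± 1.11 FPKM. S phase replication genes did not pass as a list (median 0.17; camera, adjusted p = 0.0901), with 16 of 32 higher and 6 lower. They passed in 4 of 19 alternatives, at a median of up to 0.29, with adjusted p from 0.0307 to 0.134 over all of them. Of 27 core MYC targets, 25 fell. The median over members was -0.54 (camera, adjusted p = 7.7e-07; adjusted p = 0.473 with an estimated correlation). Among them were ODC1, the first enzyme of polyamine synthesis (59.1 ± 2.59 to 23.4 ± 0.98 FPKM), and NOP16 (30.4 ± 0.41 to 10.4 ± 1.30 FPKM).

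Of 35 genes of RNA polymerase I and nucleolar ribosome biogenesis, 24 fell and 3 rose. The list median was -0.36 (camera, adjusted p = 0.00552; adjusted p = 0.516 with an estimated correlation). RRP9 and BOP1 fell, with log2 fold changes of -1.47 and -1.32, and NOLC1 rose with 1.16. Of 72 cytosolic ribosomal protein genes, 45 fell and 14 rose, or 46 and 15 adjusted over the list alone. The list's median was -0.21 (camera, adjusted p = 9.14e-04; adjusted p = 0.516 with an estimated correlation). That call was lost with quantile normalization (median -0.02; camera, adjusted p = 0.503) and after removal of the length, GC and expression trend (median -0.01; camera, adjusted p = 0.928), with a range of 1.95e-04 to 0.928 over 19 alternatives. Reads of these genes can be shared with their many pseudogenes. Nuclear genes of oxidative phosphorylation fell in 42 of 46 cases and rose in 2. Members had a median of -0.51 (camera, adjusted p = 6.19e-09; adjusted p = 0.31 with an estimated correlation). Examples were NDUFB8 of complex I (185 ± 1.26 to 65.6 ± 5.40 FPKM) and ATP5G1 of ATP synthase (138 ± 9.42 to 54.0 ± 4.68 FPKM). The median became -0.34 after removal of the trend, and the call held.

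De novo purine synthesis genes fell in 10 of 13 cases and rose in 1. The median over members was -0.39 (camera, adjusted p = 0.00918; adjusted p = 0.473 with an estimated correlation). IMPDH1 itself is a member, so the fall of the shRNA target counts toward this call, and no test without it is given here. PRPS1, which makes the ribose donor, fell from 53.9 ± 0.82 to 20.9 ± 0.61 FPKM, and PFAS had a log2 fold change of -0.71 (-0.35 with window medians subtracted). The list's median became -0.24 with quantile normalization, and the call held (camera, adjusted p = 0.0211). Purine salvage and turnover genes did not pass as a list (median -0.36, and -0.16 after removal of the trend; camera, adjusted p = 0.0692), except with a filter at a mean of 5 FPKM (median -0.43; camera, adjusted p = 0.0493; range over 19 alternatives 0.0493 to 0.308). Nor did genes of pyrimidine and deoxynucleotide synthesis pass (camera, adjusted p = 0.365). Their median of -0.10 became 0.01 when values were rescaled to 1 common sum per library, which moved the median of all genes by 0.106. In the salvage and turnover list NT5E, the ecto-5'-nucleotidase, fell from 67.6 ± 1.15 to 24.0 ± 1.59 FPKM, and in the pyrimidine list TYMS, the thymidylate synthase, fell from 288 ± 5.53 to 182 ± 5.01 FPKM.

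TGF-beta response genes fell in 14 of 20 cases and rose in 3. The list median was -0.38 (camera, adjusted p = 0.0265; adjusted p = 0.491 with an estimated correlation). The call was lost with a filter at a mean of 5 FPKM (median -0.29; camera, adjusted p = 0.106) and, at a median of -0.39, with window medians subtracted (camera, adjusted p = 0.0536), with a range of 0.0135 to 0.106 over 19 alternatives. ID1 fell from 192 ± 10.2 to 55.4 ± 4.03 FPKM, ID3 from 4.41 ± 0.13 to 0.10 ± 0.09 FPKM (log2 fold change -3.04, and -4.60 with a pseudocount of 0.1) and CTGF from 11.2 ± 1.25 to 2.80 ± 0.18 FPKM. Heat shock genes fell in 10 of 14 cases and rose in 2. The list's median was -0.50 (camera, adjusted p = 0.024; adjusted p = 0.516 with an estimated correlation). Among them were HSPA8 (611 ± 23.4 to 282 ± 43.2 FPKM) and HSP90AA1 (653 ± 23.9 to 308 ± 20.2 FPKM). With window medians subtracted their log2 fold changes went from -1.12 to -0.43 and from -1.08 to -0.63, and HSPA8 lies in the window with the lowest median. The call was lost with quantile normalization (median -0.41; camera, adjusted p = 0.119) and after removal of the trend (median -0.32; camera, adjusted p = 0.0613), with a range of 0.00962 to 0.119 over 19 alternatives. Genes often used as references also passed, with 8 of 15 lower and 3 higher. Members had a median of -0.28 (camera, adjusted p = 0.0474; adjusted p = 0.473 with an estimated correlation). ACTB fell from 2692 ± 127 to 1154 ± 67.7 FPKM and TUBA1B from 1795 ± 44.0 to 732 ± 20.5 FPKM. This call was lost in 8 of 19 alternatives (adjusted p 0.02 to 0.368 over all, with a median of -0.04 under quantile normalization), including those without control replicate 1 (0.0505), without IMPDH1 shRNA replicate 1 (0.0515) and without IMPDH1 shRNA replicate 3 (0.0639).

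Lists tied to invasion moved in both directions and did not pass as lists. Mesenchymal and EMT genes rose in 9 and fell in 14 of 28 cases (camera, adjusted p = 0.57), with SPARC falling from 191 ± 5.10 to 63.3 ± 4.38 FPKM and the receptor AXL from 103 ± 0.59 to 39.9 ± 1.61 FPKM, while the collagen cross-linking enzyme LOX rose from 0.81 ± 0.11 to 6.43 ± 0.93 FPKM. Extracellular matrix genes rose in 10 and fell in 7 of 20 cases, or 11 and 7 adjusted over the list alone (camera, adjusted p = 0.496), and their median of 0.15 (-0.03 without a filter) and mean of -0.19 differ in sign. THBS1 (147 ± 4.09 to 16.2 ± 1.20 FPKM), FBN1 (12.5 ± 0.06 to 2.72 ± 0.25 FPKM) and, outside the list, FSTL1 (146 ± 0.94 to 41.6 ± 0.66 FPKM) fell. Matrix proteases and inhibitors (camera, adjusted p = 0.496) held falls in MMP9 (log2 fold change -2.35, and -3.91 with a pseudocount of 0.1) and rises in MMP15 (2.02) and MMP16 (1.63). Genes associated with YB-1 rose in 11 and fell in 11 of 25 cases (camera, adjusted p = 0.936), with a median of 0.08 (-0.06 after removal of the trend) and a mean of -0.04, and included rises in the drug exporter ABCB1 (1.40 ± 0.11 to 7.49 ± 0.63 FPKM) and falls in ITGA6 (10.1 ± 0.71 to 1.99 ± 0.10 FPKM). Targets of HIF and glycolysis genes rose in 11 and fell in 17 of 32 cases (camera, adjusted p = 0.189), with NDRG1 rising from 68.9 ± 3.91 to 235 ± 37.2 FPKM and CA9 falling from 3.59 ± 0.45 to 0.50 ± 0.21 FPKM.

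The remaining lists did not pass either. The camera adjusted p was 0.0975 for actin cytoskeleton and adhesion genes, 0.134 for lysosome and autophagy genes (0.0307 after removal of the trend; range over 19 alternatives 0.0307 to 0.327), 0.275 for immediate early genes, 0.365 for replication-dependent histones, 0.554 for the unfolded protein response, 0.644 for YAP and TEAD targets, 0.659 for p53 targets and 0.936 for NRF2 targets, whose median of 0.02 (-0.16 without a filter) and mean of -0.09 differ in sign. Single members moved widely, as with FOSL1, an AP-1 subunit, which fell from 131 ± 4.24 to 23.3 ± 2.11 FPKM, and JUND, another, which rose from 28.2 ± 3.98 to 123 ± 0.92 FPKM. Markers of renal lineage rose in 5 and fell in 1 of 9 cases, or 5 and 2 adjusted over the list alone (camera, adjusted p = 0.0901). Among them PAX8, a transcription factor of the nephron, rose from 29.5 ± 0.35 to 77.3 ± 3.33 FPKM. Epithelial markers rose in 5 and fell in 2 of 10 cases (camera, adjusted p = 0.147; 0.0253 without a filter; range over 19 alternatives 0.0253 to 0.622). Of these markers, the tight junction gene CLDN1 rose from 20.9 ± 0.49 to 69.6 ± 5.81 FPKM. JUP was listed at 0 in all 3 control libraries and at 6.83 ± 0.67 FPKM in the IMPDH1 shRNA group (log2 fold change 3.87, and 6.11 with a pseudocount of 0.1). Zeros in a whole group escape the search for suspect zeros. Whether JUP was absent from the control cells or its estimates failed therefore stays open. Few markers of other cells reached 1 FPKM. No endothelial marker of 12 reached 1 FPKM in either group's mean, 2 of 19 immune cell markers did (CD68, at 18.1 ± 0.41 and 21.7 ± 0.73 FPKM, with a log2 fold change of 0.25 that became 0.61 with window medians subtracted and 0.51 after removal of the trend, and CSF1R, whose call was lost with window medians subtracted; limma, adjusted p = 0.181), 1 of 13 erythroid and hepatic markers did (SERPINA1, at 30.6 ± 1.81 and 25.5 ± 1.71 FPKM, whose call was lost in the same way; limma, adjusted p = 0.947) and 3 of 12 neural and HEK markers did (camera, adjusted p = 0.0975; 0.0416 after removal of the trend; range over 18 alternatives 0.0416 to 0.351).

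**Figure D3:**
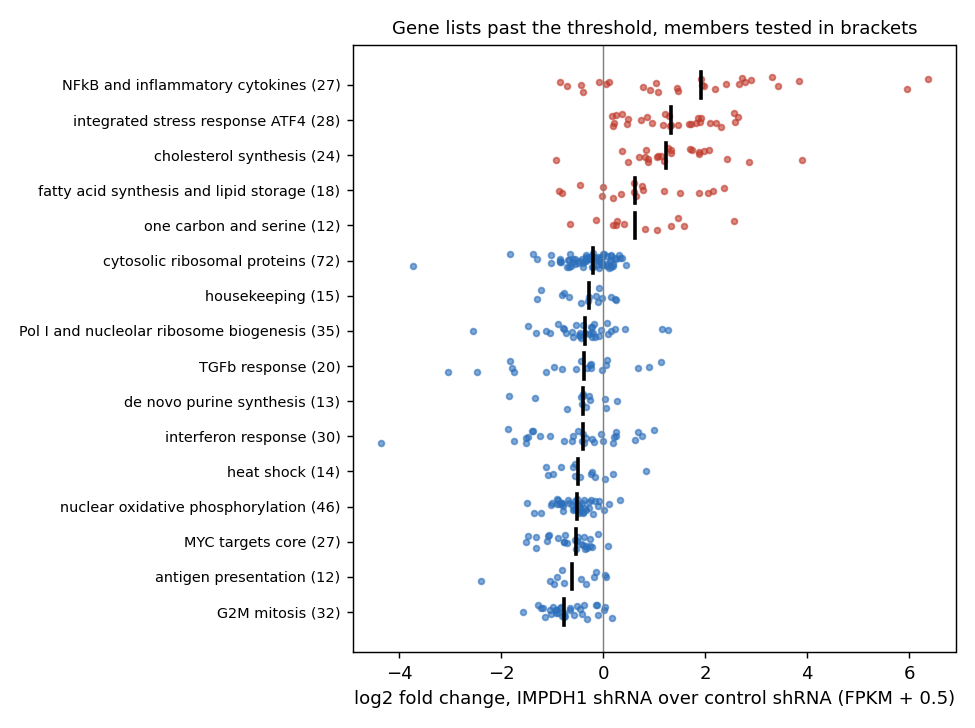
Log2 fold change (IMPDH1 shRNA over control shRNA, on FPKM + 0.5) of each tested member of the 16 gene lists past an adjusted p of 0.05 by camera with a preset correlation of 0.01, with list medians as black bars and tested members in brackets. Lists called higher are red and lists called lower are blue; medians run from 1.92 for NF-kB and cytokine genes to -0.77 for G2 and mitosis genes, and the ribosomal protein median of -0.21 became -0.01 after removal of the length, GC and expression trend.

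With an estimated correlation, camera called 0 of the 35 lists past an adjusted p of 0.05 and 5 at an unadjusted p under 0.05, against 16 and 19 with the preset correlation and 34 past the adjusted threshold by fry. The estimated correlation was -0.0206 for cholesterol synthesis and -0.049 for fatty acid synthesis and lipid storage, below the preset 0.01. A higher correlation therefore does not account for the loss of these calls. In the other called lists it ran from 0.0198 to 0.483. COL7A1 and FAT1 were listed at 0 in the 3 control libraries and in IMPDH1 shRNA replicate 1, beside 70.3 and 71.5 FPKM (COL7A1) and 35.5 and 35.02 FPKM (FAT1) in the other two, and were chosen after their values were seen.

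**Figure D4:**
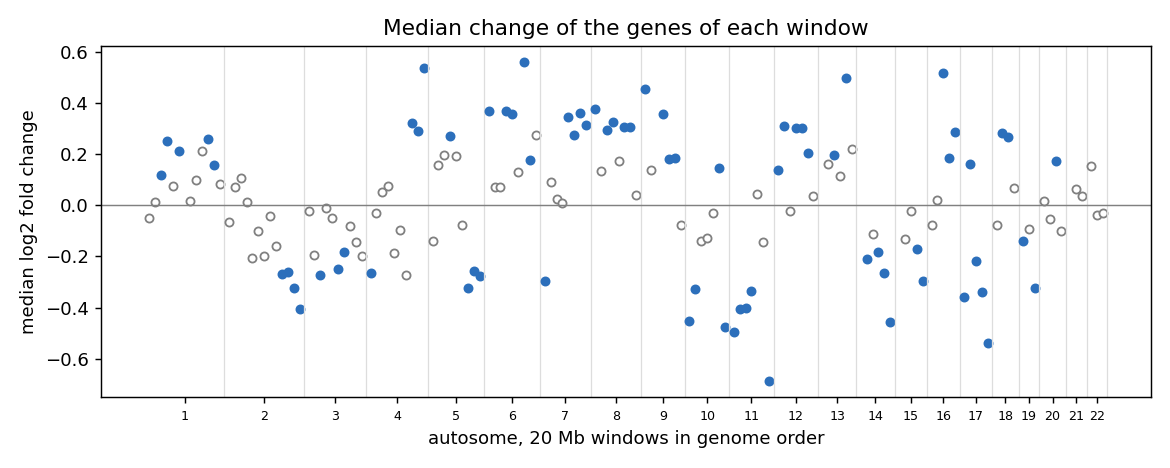
Median log2 fold change of the tested genes in each of 146 windows of 20 Mb along the autosomes, in genome order, with filled points for the 74 windows whose median lay apart from randomly drawn genes (permutation test, adjusted p under 0.05) and open points for the rest. Window medians range from -0.69 (chromosome 11, 120 to 140 Mb) to 0.56 (chromosome 6, 120 to 140 Mb).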

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

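Removing the length, GC and expression trend, subtracting window medians and setting suspect zeros to missing were chosen after seeing the data; the other alternatives were not. IMPDH1 stayed lower and past the threshold in all 19 alternatives, with log2 fold changes from -1.67 (trend removed) to -2.21 (window medians subtracted) and from -1.83 to -1.89 when 1 library was left out. The count of changed genes was 8008 and lay between 6273 (mean of at least 5 FPKM) and 9094 (no filter), with 7449 to 7884 when 1 library was left out. Of the 8008, 6460 were also called after window medians were subtracted, 6337 of them in the same direction, and 6805 after the trend was removed, 6767 of them in the same direction. With the filter at 5 FPKM, where fewer genes are tested, genes changed at least 2-fold went from 1214 to 771, with 371 higher and 400 lower. Rescaling each library to 1 common sum moved the median of all genes by 0.106 (log2) and the share of rises among calls from 48.4% to 57.4%, with 839 rises and 553 falls of at least 2-fold in place of 592 and 622; relative to that shift no list past the threshold turned direction. Called lists numbered 16, from 14 to 18 in these alternatives and 15 to 16 when 1 library was left out, but 0 with camera's estimated correlation and 34 with fry, which asks another question. Reversed results were SERPINA1 with window medians subtracted (log2 fold change 0.0060, limma adjusted p = 0.947, where its window's median nearly equals its own change) and, by fry against camera's direction, extracellular matrix (median 0.15, fry adjusted p = 8.19e-04), NRF2 targets (median 0.016, fry adjusted p = 0.0151) and YB-1 associated genes (median 0.081, fry adjusted p = 0.00219); the cause was not tested. Of 151 named genes other than IMPDH1, 5 calls were lost, that of SERPINA1 included, and 2 gained over all alternatives. Same-numbered libraries did not deviate together (correlations across genes of -0.134, -0.112 and -0.133), no library correlated best with its own number, and the replicate block gave 7793 calls. The real split gave 8008 genes, 1214 at least 2-fold and 16 lists, the highest other split 1, 1 and 12, and 1 of the 10 splits of the 6 libraries reached each real count, the real one itself; 10 splits are too few for a share under 0.05. Depth is unknown between groups, so no limit on low genes can be given.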

Other observations

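Pathways named in the deposited annotation were tested after the gene lists had been seen, with camera at the preset correlation over 268 pathways of at least 10 tested genes, and 11 passed. Proteasome genes, the core of regulated protein breakdown, fell in 35 of 39 cases and rose in 1 (median log2 fold change -0.55; camera, adjusted p = 2.58e-07; adjusted p = 0.774 with an estimated correlation), and this call held after the length, GC and expression trend was removed (median -0.48; camera, adjusted p = 2.35e-06). Spliceosome genes fell in 73 of 124 cases and rose in 20 (median -0.23; camera, adjusted p = 0.00748; adjusted p = 0.849 with an estimated correlation), a call that was lost after the trend was removed (median -0.17; camera, adjusted p = 0.0519). Steroid biosynthesis rose in 14 of 16 cases (median 1.16; camera, adjusted p = 8.36e-05; adjusted p = 0.774 with an estimated correlation). Ribosome and oxidative phosphorylation pathways passed (camera, adjusted p = 5.25e-05 and 6.7e-05), but not after the trend was removed (camera, adjusted p = 0.433 and 0.0892). Pathways named for Parkinson's, Huntington's and Alzheimer's disease passed as lower. Rheumatoid arthritis passed as higher, with 29 rises and 8 falls among 43 genes (camera, adjusted p = 0.00288). Arrhythmogenic right ventricular cardiomyopathy (23 falls, 5 rises) and olfactory transduction (12 falls, 0 rises) passed as lower (camera, adjusted p = 0.0273 for each). Alzheimer's disease and olfactory transduction did not pass after the trend was removed (camera, adjusted p = 0.0587 and 0.0519). Other pathways close to called lists did not pass. The camera adjusted p was 0.71 for NF-kappa B signaling (median 0.05), 0.233 for TNF signaling and 0.206 for antigen processing. It was 0.708 for the cell cycle (median -0.06), 0.146 for purine metabolism and 0.109 for ribosome biogenesis.

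In the position, low-value and zero patterns below, the tests of copy number, of trends over windows, of low-value steps and of zeros were chosen only after the result was seen. Genes of the same 20 Mb window shifted together: 74 of 146 windows lay apart from randomly drawn genes, 32 lower and 42 higher (22 of them at the smallest p that 10000 draws can give, 0.0001), and the SD of window medians was 0.248 against at most 0.115 in 1000 shuffles of gene positions. After the trends were removed the SD was 0.23 against at most 0.108 in shuffles, and without genes changed at least 2-fold it was 0.209 against at most 0.107, which argues against trends or strongly regulated neighbours as the whole cause. Window medians of higher- and lower-expressed genes correlated across windows with r = 0.78 against at most 0.277 in shuffles, before the trends were removed. Any shift shared by the genes of a window gives such a correlation, so it does not single out a cause. A candidate explanation is that the cells of the 2 groups differ in DNA copy number over parts of chromosomes. An example is chromosome 11, where the median over all genes was -0.35. Regulation over whole domains, an effect of the IMPDH1 shRNA itself, would give the same correlation and was not tested, and no DNA was analysed here. IMPDH1 lies in a window with a median of 0.36, so its position does not account for its fall.

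Low values shared a step of 1 read within a group but not between groups. The most common ratio held at least 15.1% of low genes in each of the 6 pairs of libraries within a group. In the 9 pairs between groups it held at most 8.8%. A candidate explanation is that values of the 2 groups were scaled per gene by different effective lengths or bias corrections. Such scaling would set the groups apart in every library, so limma could not tell it from an effect of the shRNA. Among the lists that fell were 2 of short transcripts, although replication-dependent histones (median length 724 bases) did not pass, and the trend on length, GC and expression was tested as their cause. Nuclear oxidative phosphorylation genes (median transcript length 1266 bases) stayed past the threshold after the trend was removed (camera, adjusted p = 1.66e-05), with a median of -0.34 after -0.51 and an SD over members of 0.34 after 0.36, which argues against the trend as the whole cause for this list, although the wider annotated pathway of 101 genes lost its call (median -0.18; camera, adjusted p = 0.0892). Ribosomal protein genes (median length 1176 bases) lost theirs because their median went from -0.21 to -0.01 while the SD over members was 0.59 before and after, so for that list the trend stays open.

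Exact zeros stood beside high values within a group in 11 cases over 9 genes (among them COL7A1, FAT1, HNRNPC, NASP, NETO2, RNF213 and UBTF, named because of these values). HNRNPC, an abundant RNA-binding protein gene, was listed at 146, 146 and 0 FPKM in the control libraries. The other libraries of such a group could agree closely, as in NETO2 (50.4 and 50.8 FPKM beside 0) and NASP (56.9 and 56.4 FPKM beside 0 in the control group). A count of values above 0 but under 5% of the highest value of the group gave 12 over all genes, which decides nothing about these genes, so whether the zeros are failed estimates stays open. Setting the zeros to missing gave 8023 changed genes in place of 8008.

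The other 9 splits of the 6 libraries called at most 1 gene but 8 to 12 gene lists by camera with the preset correlation. Each of these splits still sets 2 libraries of one group against 1. Why they call lists was not tested, and a call of a list by this test is a weak statement by itself.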
